A study of Mus musculus with 21 samples.

How the data were processed

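The deposited per-library signal was given by the authors as normalized scaled reads per base for each gene, and per the submitters' processing notes it came from kallisto 0.43.0 and sleuth 0.28.1 on GRCm38. The annotation release and the roles of these tools are not given in the sources used here. Per the labels, P21 libraries were made with the Illumina TruSeq RNA Sample Prep Kit and P60 libraries with the NEXTflex Rapid Directional RNA-Seq Kit, from Trizol RNA of frozen spinal cord. The values had been scaled within each age by the authors, with median-of-ratios factors of 0.984 to 1.03 at P21 and 0.983 to 1.01 at P60, and were not scaled again. The authors' tables hold, per the file headers, effects on the natural log scale of value + 0.5 with their standard errors, and these were divided by the natural log of 2 to give log2. They also hold a p-value and a q-value per gene that the authors computed before deposit, and both were used as deposited.

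Gene names and positions were joined by Ensembl identifier from the GENCODE M21 annotation of GRCm38, with 24877 of 25127 identifiers named. The per-library values gave the mean in the authors' tables (within 1e-06) for 16483 of 18101 genes at P21 and 15368 of 16928 at P60. They differed for 901 and 871 genes, and 717 and 689 genes of the authors' tables were absent from the per-library values.

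Group labels, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. Values were taken to log2(value + 0.5). A gene was tested if it reached 5 in at least 4 libraries at P21 or 3 at P60. The 3 genotypes of an age were fitted together with limma-trend, moderated t tests were 2-sided, and the adjusted p is that of Benjamini and Hochberg with a threshold of 0.05. Every adjusted p of a gene in the text is from limma. The SE is the moderated standard error of the log2 change, and the SD is over libraries on the deposited scale. The age difference is the interaction of genotype and age in a fit of all 6 groups. Overlap between ages was tested with a one-sided Fisher exact test. Genes without overlap are those for which every library of one group lies above every library of the other.

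The 28 gene lists were cholesterol biosynthesis, SREBP regulation and sterol uptake, fatty acid synthesis, cholesterol efflux and LXR targets, myelin and mature oligodendrocyte, newly formed oligodendrocyte, oligodendrocyte precursor, astrocyte, reactive astrocyte, homeostatic microglia, disease-associated microglia, interferon response, antigen presentation, integrated stress response, endoplasmic reticulum chaperones, necroptosis, p53 targets, neuron, motor neuron, endothelial and mural, meningeal fibroblast, Schwann cell, peripheral leukocyte, erythrocyte, immediate early, proliferation, genes of amyotrophic lateral sclerosis and frontotemporal dementia, and sex-linked genes. Each was tested with camera in limma at a preset correlation of 0.01, adjusted over the 28 lists, and also with an estimated correlation and with fry. Members were counted after adjustment over all genes and over the list alone. Only tested members enter these counts, so list genes absent from the per-library values or below the filter are left out.

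Genes named in the text follow a rule, and some genes that it selects are not reported here. For cKO against cHET these were Tardbp, Cnp, the 10 highest and 10 lowest log2 changes among genes with a symbol, adjusted p under 0.05, a mean of at least 20 in the higher group and no overlap, and up to 4 members with the smallest p of each list that passed or had at least 2 called members. For the other comparisons they were Tardbp, Cnp and the 5 highest and 5 lowest, and for the age difference the 10 smallest p. Mbp, Mog, Opalin, P2ry12, Tmem119, Ptprc, Calca, Ifit1 and Hbb-bs were named after their values were seen. So were Chat, Slc5a7, Prph, Cdkn1a and Plk2, list genes that are missing from the per-library values or differ there.

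Alternatives were a pseudocount of 5 or 0.05, no filter or a mean of at least 50, median-of-ratios scaling, quantile normalization, a fit of only the 2 groups compared or of all 6 groups, array weights, robust moderation, the authors' test, sex as a covariate at P21, removal of sex-linked genes at P60, and removal of each library in turn. Added after the data were seen were the use of only genes equal in both kinds of file, removal of P60 control 1 and P60 cHET 3 together, and list tests of the age difference. Single libraries were compared with their group by Dixon's ratio in groups of 4. The gene and list tests, without the filter and scaling, were tried on simulated log2 values with 200 changed genes. The gene test recovered 26.9% to 52.2% of genes changed by 0.5, 62.7% to 76.1% of those changed by 1 and 81.8% to 87.9% of those changed by 2, with 4 to 13 false calls per comparison. For the age difference these shares were 31.3%, 50.7% and 86.4%, with 3 false calls. Far more than 200 genes were called in the real comparisons of cKO, so these shares do not give the power there. A gene list shifted by 1 was recovered in all 6 comparisons, with 0 false lists. The simulated noise was independent between genes, so this count does not show how often correlated genes make a list pass. Software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.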

Results

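RNA from whole spinal cord was sequenced in 21 C57BL/6 mice to ask how loss of TDP-43, an RNA-binding protein linked to amyotrophic lateral sclerosis and frontotemporal dementia, alters gene expression when it is removed from oligodendrocytes. Tardbp, the gene that encodes TDP-43, was deleted with Cnp-Cre, a recombinase expressed in cells of the oligodendrocyte lineage. Control mice carried 2 floxed Tardbp alleles and no Cre, heterozygous mice (cHET) carried Cnp-Cre and 1 floxed allele, and knockout mice (cKO) carried Cnp-Cre and 2 floxed alleles. At postnatal day 21 (P21) each genotype had 4 mice, labelled 2 female and 2 male, and at about day 60 (P60) each genotype had 3 mice. Each library was labelled with its own mouse number, so replicates were separate animals. The P60 controls were labelled female and 74 days old, whereas the P60 cHET and cKO mice were labelled male and 60 to 65 days old. The deposited values were normalized scaled reads per base for 25127 genes. They summed to between 26.9 M and 29.2 M in the P21 libraries and between 12.5 M and 13.8 M in the P60 libraries (M for 1e6). These sums follow normalization, so the number of reads behind them is unknown. Between 20366 and 20880 genes had a value above 0 at P21, and between 19645 and 20138 at P60. Log2 values of replicates correlated across genes at up to 0.981 at P21 and up to 0.982 at P60, and those of different genotypes at up to 0.980 and 0.983. Genes of the mitochondrial genome took 6.4% to 8.12% of the values at P21. At P60 that share was 14.6% to 17.9% in cKO, 11.4% to 16.2% in cHET and 10.2% to 16.1% in control libraries.

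Tardbp (ENSMUSG00000041459; GRCm38 chromosome 4, 148612382 to 148627019) was examined first in every library. At P21 its values were 2198, 2283, 2415 and 2155 in controls, 2068, 2236, 2030 and 2231 in cHET, and 1731, 1880, 1753 and 1639 in cKO mice. At P60 they were 828, 884 and 937 in controls, 925, 932 and 906 in cHET, and 831, 794 and 783 in cKO mice. Against cHET, Tardbp fell by 0.29 ± 0.06 (SE) on the log2 scale at P21 (adjusted p = 2.5e-03), and every cKO library lay below every cHET library. At P60 it fell by 0.20 ± 0.06 (adjusted p = 0.040), again without overlap. The P60 call ended in 7 of 9 fits that left out 1 library, which were those without control 2 (adjusted p = 0.059), cHET 1 (0.099), cHET 2 (0.11), cHET 3 (0.060), cKO 1 (0.059), cKO 2 (0.11) or cKO 3 (0.10). In the authors' deposited table the P60 q was 0.063. Against control, Tardbp fell by 0.37 ± 0.06 at P21 (adjusted p = 3.3e-04). The P60 difference of -0.14 ± 0.06 did not pass (adjusted p = 0.14), nor did cHET against control at either age (-0.08, adjusted p = 0.81, and 0.06, adjusted p = 0.99). The cord holds many cell types outside the Cnp-Cre lineage, and gene-level values do not resolve the floxed exon.

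Cnp (ENSMUSG00000006782; chromosome 11, 100574904 to 100591729) encodes a myelin enzyme and is the locus into which Cre was placed. It was 84250 ± 5160 (SD, n = 4) in P21 controls, 46723 ± 2131 in cHET and 52800 ± 4262 in cKO mice. At P60 (n = 3) it was 15210 ± 579, 8830 ± 95.2 and 11366 ± 715. Both Cre-carrying genotypes fell against control, cHET by 0.85 ± 0.07 at P21 (adjusted p = 9.5e-05) and by 0.78 ± 0.06 at P60 (adjusted p = 1.1e-03). In cKO the values were -0.68 (adjusted p = 4.2e-06) and -0.42 (adjusted p = 3.8e-04). Between cKO and cHET, which both carry Cre, Cnp rose by 0.36 ± 0.06 at P60 (adjusted p = 1.1e-03). The P21 difference of 0.17 ± 0.07 did not pass (adjusted p = 0.084), although it passed after quantile normalization (0.23, adjusted p = 6.1e-03) and without cKO 1 (0.22, adjusted p = 0.025).

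**Figure D1:**
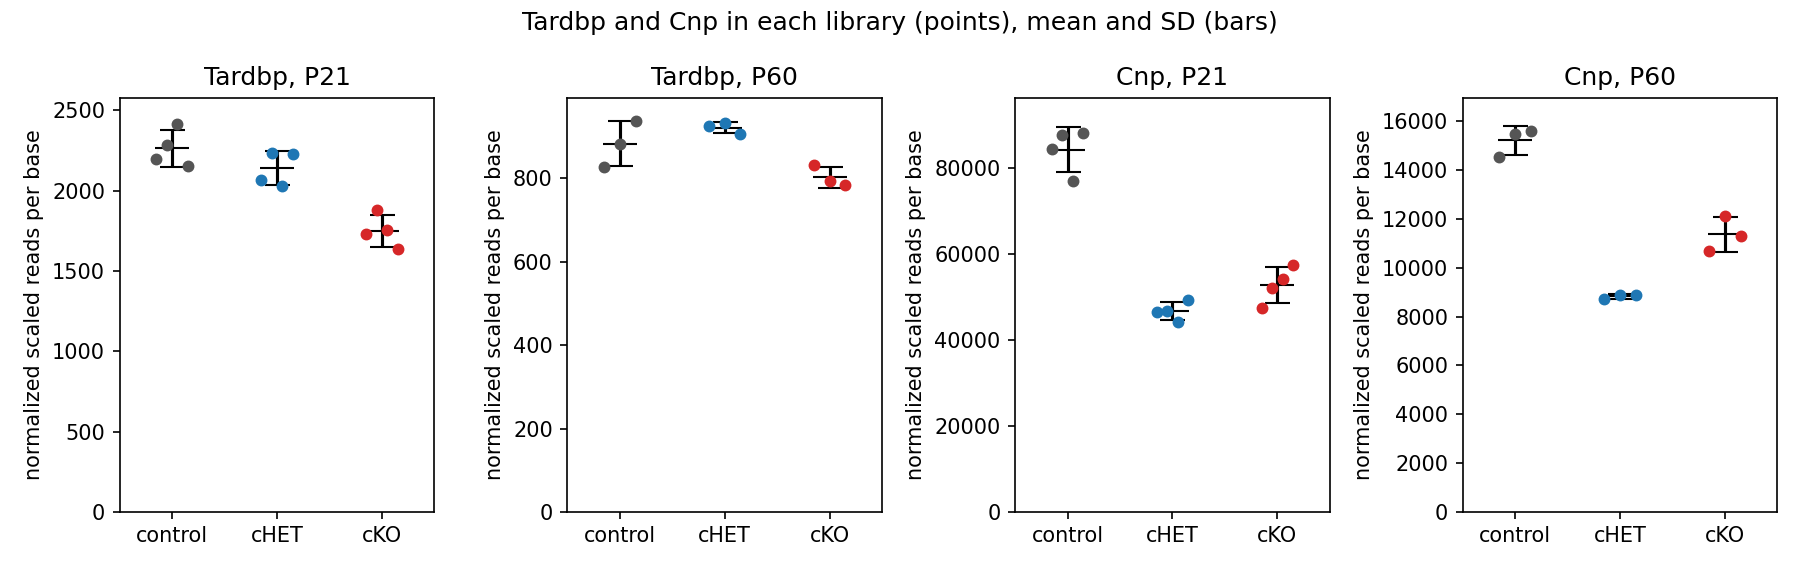
Tardbp and Cnp in each library at P21 (4 mice per genotype) and P60 (3 mice per genotype), in normalized scaled reads per base, with the mean and SD of each genotype. The cKO libraries lie below the cHET libraries for Tardbp at both ages, and for Cnp both Cre-carrying genotypes lie below control.

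The comparison of cKO with cHET at P21 isolates the second floxed allele, because both genotypes carry Cnp-Cre. Every tested gene of the cholesterol biosynthesis list fell in cKO cord, among them Cyp51 (lanosterol demethylase), Sqle (squalene epoxidase) and Hmgcs1 (cytosolic HMG-CoA synthase). Of 25 genes of myelin and the mature oligodendrocyte 16 fell and 4 rose, and 22 of 23 genes of disease-associated microglia rose. Gpnmb, a phagocyte glycoprotein, rose by 40.1-fold. Apoe, the main lipid carrier of the brain and cord, rose from 48707 ± 4301 to 159730 ± 10732 (SD, n = 4), which is 3.28-fold. In total 4059 of 17989 tested genes changed, 2266 up and 1793 down, and 830 of these rose and 113 fell by at least 2-fold. The upward share of 55.8% became 46.8% after quantile normalization (2032 up, 2314 down). The groups did not overlap for 22.6% of the genes, against 2.86% by chance. The authors' deposited table holds 4316 genes at q under 0.05 (2352 up, 1964 down), including 93.5% of the genes called here. The rule that selects genes for this text favours small p and no overlap, and of the 109 selected genes that passed, 103 showed no overlap between the 4 cKO and the 4 cHET libraries.

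Wisp2, a matricellular protein of the CCN family, rose from 12.9 to 1031 (6.80 ± 0.59, adjusted p = 9.7e-07). Lilrb4a and Lilr4b, receptors of myeloid cells, rose by 6.13 and 6.31. Atp6v0d2, a subunit of the vacuolar proton pump, rose by 6.45, Apoc2, a lipoprotein cofactor, by 6.47, Cd300lb, a myeloid receptor, by 5.31 and Klrb1b, a lectin-like receptor, by 5.28. Gpnmb (chromosome 6, 49036546 to 49070929) rose from 75.1 ± 48.4 to 2763 ± 697 (SD), a log2 change of 5.33 ± 0.31 (adjusted p = 1.6e-08). Ifi211, an interferon-inducible gene, passed as well and was listed at 0 in every cHET library. Xpo7, a nuclear transport receptor, was listed at 0 in every cHET library too, but its call (adjusted p = 0.037) rests on values that differ from those behind the authors' deposited table, where its log2 change was -0.10. The largest decreases included Nkx2-9 (chromosome 12, 56611389 to 56613284), a homeobox transcription factor, which fell by 4.50 ± 0.17 from 482 to 20.9 (adjusted p = 6.4e-10). Klk6 (chromosome 7, 43824499 to 43832030), a serine protease of mature oligodendrocytes, fell by 3.78 ± 0.20 from 4953 ± 282 to 383 ± 155 (adjusted p = 7.5e-09). Itgb4 (integrin beta 4), Cdkn1c (an inhibitor of the cell cycle), Dnah8 (an axonemal dynein), the protease Tmprss5, the transcription factor Tbx10 and the unnamed gene 7420461P10Rik fell by 2.13 to 2.77. Rps27a-ps2, a pseudogene that can share reads with Rps27a, was at -8.60 and is uncertain, and Gm49387 was listed at 0 in every cKO library.

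Cholesterol and lipid genes moved in both directions. All 20 measured cholesterol biosynthesis genes fell (20 adjusted over the list alone), with a median of -0.82 (adjusted p = 2.1e-21; adjusted p = 0.061 with an estimated correlation). Hmgcs1 fell by 1.10 ± 0.09, Cyp51 from 3105 ± 314 to 1492 ± 96.7 (SD), Sc5d by 0.89 and Sqle by 0.88. Hmgcs1 is among the genes whose values differ between the per-library file and the authors' deposited table. Of 11 genes of SREBP regulation and sterol uptake, 2 rose and 4 fell (the same counts adjusted over the list alone), and the list did not pass (adjusted p = 0.48, median -0.01). The sterol transporter Stard4 fell by 0.69 ± 0.13 (adjusted p = 1.3e-03) and Insig1, which retains the SREBP complex in the endoplasmic reticulum, by 0.56, whereas Npc2, which carries cholesterol out of lysosomes, rose by 0.38. Srebf2, the master transcription factor of sterol synthesis, was taken from the authors' deposited table, where it was at -0.38 (q = 8.5e-09). No result from per-library values is given for it here. It belongs to the list of SREBP regulation, which was fixed with more genes than the 11 tested, so the list test may lack it. Of 16 fatty acid synthesis genes 9 fell and 0 rose (11 down and 1 up adjusted over the list alone), median -0.33 (adjusted p = 4.2e-06; adjusted p = 0.077 with an estimated correlation). Scd1, a desaturase, fell by 0.65 and Acly, which supplies cytosolic acetyl-CoA, by 0.55. Of 14 genes of cholesterol efflux and LXR response 8 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 1.0e-03; adjusted p = 0.061 with an estimated correlation). Apoe rose by 1.72 ± 0.08 (adjusted p = 2.4e-09), Apoc1 by 2.96 and Mylip, a ubiquitin ligase, by 1.20, while Cyp27a1, a sterol hydroxylase, fell by 1.12.

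Of 25 genes of myelin and the mature oligodendrocyte 16 fell and 4 rose (18 down and 4 up adjusted over the list alone), with a median of -0.45 (adjusted p = 9.4e-09; adjusted p = 0.15 with an estimated correlation). The gap junction protein Gjb1 fell by 1.45 ± 0.07, Hapln2, a link protein of nodes of Ranvier, by 1.21 ± 0.06, Ermn (ermin) by 1.09 and Fa2h, which makes hydroxylated myelin lipids, by 0.91. Among genes chosen after their values were seen, Mbp, myelin basic protein, was at -0.42 (adjusted p = 5.0e-03) and Opalin at 0.33 (adjusted p = 0.013). Of 10 genes of newly formed oligodendrocytes 6 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 2.5e-03, and adjusted p = 0.26 with an estimated correlation). The calcium-sensing receptor Casr rose by 1.21 and Gpr17, a receptor of differentiating oligodendrocytes, by 0.63. Of 14 precursor genes 8 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 4.5e-05, and adjusted p = 0.061 with an estimated correlation). The proteoglycan Cspg4 (NG2) rose by 1.29 ± 0.05 and the matrix protein Matn4 by 0.68. Proliferation genes rose for 8 of 12 members (9 adjusted over the list alone; adjusted p = 2.0e-04, and adjusted p = 0.29 with an estimated correlation), among them the kinase Cdk1, by 1.28, and Ube2c, by 0.84.

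Glial activation and immune genes rose. In the list of disease-associated microglia 22 of 23 genes rose, with 22 adjusted over the list alone and a median of 3.28 (adjusted p = 1.8e-31), and this list also passed with an estimated correlation (adjusted p = 0.027). Tyrobp, a signalling adaptor of myeloid receptors, and Lpl, lipoprotein lipase, each rose by 3.18, and the lysosomal proteases Ctsz and Ctsd by 2.61 and 2.42. Of 18 genes of homeostatic microglia 15 rose and 1 fell (15 and 3 adjusted over the list alone), with a median of 1.79 (adjusted p = 5.5e-15; adjusted p = 0.061 with an estimated correlation). The complement genes C1qa, C1qb and C1qc rose by 2.67 to 2.81. The decrease was in P2ry12, a purinergic receptor of resting microglia (-0.43, adjusted p = 3.7e-03). Reactive astrocyte genes rose for 17 of 18 members (17 adjusted over the list alone), median 1.69 (adjusted p = 1.6e-19; adjusted p = 0.011 with an estimated correlation). The protease inhibitor Serpina3n rose by 3.03 ± 0.11, the intermediate filament genes Vim and Gfap by 2.63 and 1.36. Of 16 general astrocyte genes 9 rose and 0 fell (9 and 2 adjusted over the list alone; adjusted p = 2.4e-04, and adjusted p = 0.061 with an estimated correlation), for example the transcription factor Sox9 (0.79) and the water channel Aqp4 (0.71). Interferon response genes rose for 17 of 19 members (18 adjusted over the list alone), median 1.68 (adjusted p = 4.9e-10; adjusted p = 0.22 with an estimated correlation), with the chemokine Cxcl10 at 3.12 and Lgals3bp at 2.76. The mean log2 value of the interferon response list was 8.95 and 9.03 in cKO 2 and 3, labelled male, and 7.41 and 7.52 in cKO 1 and 4, labelled female, against 5.83 to 6.84 in cHET mice. Of 14 antigen presentation genes 12 rose and 0 fell, the same adjusted over the list alone (adjusted p = 1.1e-10; adjusted p = 0.061 with an estimated correlation). The immunoproteasome subunit Psmb8 rose by 2.61 and B2m, the light chain of MHC class I, by 1.97.

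Stress and cell death genes changed in part. Of 22 integrated stress response genes 6 rose and 2 fell (7 and 4 adjusted over the list alone; adjusted p = 0.18). The transcription factor Atf3 rose by 3.39 ± 0.22 and Nupr1, a stress-induced nuclear protein, by 1.72. Endoplasmic reticulum chaperones did not pass, with 1 of 12 genes up, also adjusted over the list alone (adjusted p = 0.81, test downward, median -0.06, mean 0.01). Of 9 necroptosis genes 5 rose, also adjusted over the list alone (adjusted p = 7.2e-05; adjusted p = 0.061 with an estimated correlation), including Casp8 (1.85 ± 0.11), an apical caspase, and the TNF receptor Tnfrsf1a (1.30). Of 12 tested p53 targets 3 rose (4 up and 1 down adjusted over the list alone; adjusted p = 0.099), among them Bbc3, which promotes apoptosis (0.72). The listed genes Cdkn1a and Plk2 are missing from the per-library values or differ there. In the authors' deposited table they were at 1.16 (q = 4.0e-04) and -0.21 (q = 0.49). The integrated stress response list passed without cHET 4 (adjusted p = 0.030) and the p53 targets list without cHET 1 (0.037). Immediate early genes, listed as a possible sign of handling, rose for 3 of 10 members (4 adjusted over the list alone; adjusted p = 0.033, and adjusted p = 0.53 with an estimated correlation). Whether handling caused this was not tested. Junb rose by 0.90 and Btg2 by 0.87. That list's call ended without cHET 2 (adjusted p = 0.0997), cHET 3 (0.0786), cKO 1 (0.0689) or cKO 4 (0.102).

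Genes of other cells in the cord were measured beside these. Of 17 neuronal genes 13 fell and 0 rose (16 and 0 adjusted over the list alone), median -0.28 (adjusted p = 2.1e-08; adjusted p = 0.061 with an estimated correlation), such as Gad2 (-0.45) and Gad1 (-0.39), which make GABA, and Slc17a6 (-0.31), a glutamate transporter. None of 5 tested motor neuron genes changed by limma (0 adjusted over the list alone; adjusted p = 0.30, median -0.15). The listed genes Chat, Slc5a7 and Prph are missing from the per-library values or differ there. In the authors' deposited table they were at -0.10, -0.26 and -0.08 (q = 0.71, 0.39 and 0.72). Of 18 endothelial and mural genes 2 rose and 4 fell (2 and 5 adjusted over the list alone; adjusted p = 0.19), with Tagln, of contractile cells, at 1.24. Of 10 meningeal fibroblast genes 1 rose and 2 fell (2 and 3 adjusted over the list alone; adjusted p = 0.42), with Col1a2, a fibrillar collagen, at 0.38 (adjusted p = 0.012). Of 8 Schwann cell genes 3 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.25). Ncmap, a protein of noncompact myelin, rose by 2.24 and Pmp22, a peripheral myelin protein, fell by 0.60. Among 10 genes of peripheral leukocytes 1 rose, also adjusted over the list alone (adjusted p = 0.46, test upward, median -0.10, mean 0.23). It was Ptprc, which microglia also express (2.77, adjusted p = 4.2e-08). Neither the 5 erythrocyte genes nor the 8 sex-linked genes held a call (0 each adjusted over the list alone; adjusted p = 0.20, median -0.50, and adjusted p = 0.71, median -0.05). Without cHET 3 the erythrocyte list passed (median -0.74, adjusted p = 0.047). Of 21 genes linked to amyotrophic lateral sclerosis or frontotemporal dementia 2 rose and 5 fell (2 and 7 adjusted over the list alone; adjusted p = 0.036, and adjusted p = 0.23 with an estimated correlation). Grn, progranulin, rose by 2.34 ± 0.09 and Sort1, its sorting receptor, fell by 0.53. The list of ALS and FTD genes no longer passed without cHET 4 (adjusted p = 0.0676), without cKO 1 (0.0689), after quantile normalization (0.282) or on genes equal in both kinds of deposited file (0.0806).

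**Figure D2:**
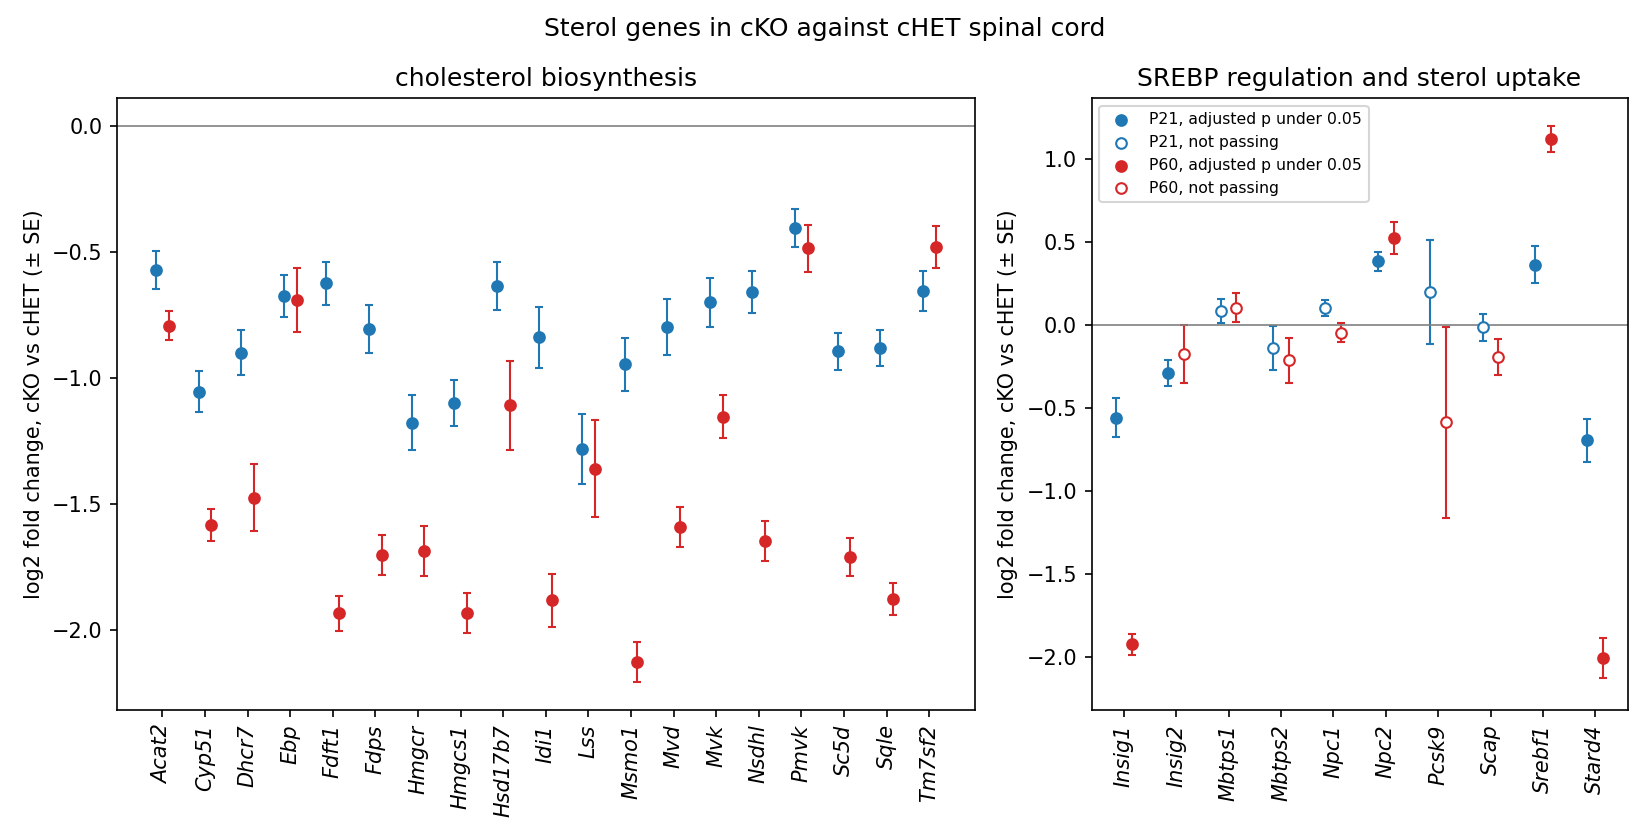
Log2 fold change of cKO against cHET, with its SE, for measured genes of cholesterol biosynthesis and of SREBP regulation and sterol uptake at P21 (blue) and P60 (red), filled where the adjusted p was under 0.05. The cholesterol biosynthesis genes shown lie below 0 at both ages.

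The same comparison at P60 placed 3 cKO against 3 cHET mice. Cholesterol biosynthesis genes again all fell, with Msmo1, a sterol demethylase, at -2.13 ± 0.08 and Sqle at -1.88 ± 0.06. Hapln2 fell from 1534 ± 166 to 184 ± 28.4 (SD, n = 3), and Apoe rose from 20010 ± 697 to 147090 ± 14465, 7.33-fold by the fitted log2 change. Gpnmb rose 65.4-fold and the macrophage lysozyme Lyz2 41.3-fold. Of 16833 tested genes 4200 changed, 2258 up and 1942 down, with 874 up and 293 down by at least 2-fold. The upward share of 53.8% became 46.1% after quantile normalization (2075 up, 2425 down). The groups did not overlap for 39.5% of the genes, against 10% by chance. The authors' deposited table holds 4352 genes at q under 0.05 (2303 up, 2049 down), including 91% of the calls made here. By the same rule, all 111 selected genes passed without overlap between the 3 cKO and the 3 cHET libraries.

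Atp6v0d2 rose by 7.28 ± 0.77 (adjusted p = 4.2e-05) and Gpnmb by 6.03 ± 0.24, from 60.2 ± 20.6 to 3870 ± 847 (SD; adjusted p = 4.1e-08). Wisp2 rose by 5.93, the integrin Itgax (CD11c) by 5.84, Lilr4b by 5.82, Cst7, an inhibitor of cathepsins, by 5.63, Clec7a, a receptor for fungal glucans, by 5.53 and Lyz2 by 5.37. Arsi, a sulfatase, rose by 5.58 and Ly9, a receptor of immune cells, by 5.33. At the other end Nkx2-9 fell by 6.34 ± 0.20 to 1.20 (adjusted p = 2.0e-08) and Klk6 fell by 4.09 ± 0.20, from 3741 ± 339 to 228 ± 77 (adjusted p = 1.6e-07). Anln, a septin-binding protein found in myelin, fell by 3.97 ± 0.14 from 490 to 30.5, Serpinb1a, a protease inhibitor, by 3.83, Pdlim1, a cytoskeletal adaptor, by 3.82 and the unnamed genes 4933413G19Rik and Gm19963 by 3.73 and 3.40. The values of AL670603.1 (-6.16), Gm15725 (-4.03) and the pseudogene Apoo-ps (-4.54) are uncertain, since such sequences can share reads with other genes.

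For sterol genes the counts were 20 of 20 cholesterol biosynthesis genes down (20 adjusted over the list alone), median -1.62 (adjusted p = 1.1e-24; adjusted p = 0.052 with an estimated correlation). Fdft1, squalene synthase, was at -1.93 ± 0.07, with values that differ from those behind the authors' deposited table. Of 11 genes of SREBP regulation and sterol uptake 2 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.070, median -0.19, mean -0.52). The list of SREBP regulation and sterol uptake passed without cHET 3 (adjusted p = 0.046). Stard4 fell by 2.01 and Insig1 by 1.92 ± 0.06, while Srebf1, the SREBP gene of fatty acid synthesis, rose by 1.12 ± 0.08. In the authors' deposited table Srebf2 was at -1.18 (q = 1.7e-76), and the test of the SREBP list may lack it here too. Fatty acid synthesis genes fell for 13 of 16 members and rose for 1 (14 and 1 adjusted over the list alone; adjusted p = 7.8e-08, and adjusted p = 0.12 with an estimated correlation), with Scd1 at -1.06 and Acss2, which activates acetate, at -0.89. In the efflux and LXR list 7 of 14 genes rose and 1 fell (9 and 3 adjusted over the list alone; adjusted p = 4.5e-04, and adjusted p = 0.18 with an estimated correlation). Apoc1 rose by 5.08, Apoe by 2.87 ± 0.08 and the cholesterol exporter Abca1 by 2.84 ± 0.09.

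Mature oligodendrocyte genes fell for 18 of 25 members and rose for 3 (19 and 3 adjusted over the list alone), median -0.66 (adjusted p = 2.5e-09; adjusted p = 0.13 with an estimated correlation). Hapln2 fell by 3.06 ± 0.11, Gjb1 by 2.43, the axon-glial adhesion protein Cntn2 by 2.05 and Fa2h by 1.5. Chosen after their values were seen, Mog, a surface protein of the outer myelin sheath, was at -0.67 (adjusted p = 3.0e-04) and Opalin at 1.51 (adjusted p = 1.5e-05). Of 10 genes of newly formed oligodendrocytes 7 rose and 2 fell, also adjusted over the list alone (adjusted p = 6.8e-03; adjusted p = 0.10 with an estimated correlation). Gpr17 rose by 1.98 ± 0.08 and Bcas1, a marker of early myelinating cells, fell by 0.94. Of 14 precursor genes 11 rose and 1 fell, also adjusted over the list alone (adjusted p = 2.5e-07; adjusted p = 0.066 with an estimated correlation), with Cspg4 at 1.41 and the matrix protein Tnr at 1.04. Proliferation genes rose for 7 of 11 members (8 adjusted over the list alone; adjusted p = 3.1e-04, and adjusted p = 0.15 with an estimated correlation), among them Ccnb1, a mitotic cyclin (2.14), and Mki67 (1.92).

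Disease-associated microglia genes rose for 21 of 22 members (22 adjusted over the list alone), median 3.40 (adjusted p = 1.7e-23; adjusted p = 0.066 with an estimated correlation). Cd68, a lysosomal glycoprotein, rose by 4.03 ± 0.11 and the lipid receptor Trem2 by 3.52 ± 0.13. Of 18 homeostatic microglia genes 13 rose and 4 fell, also adjusted over the list alone (adjusted p = 2.5e-07; adjusted p = 0.20 with an estimated correlation). C1qa rose by 2.91 and the fractalkine receptor Cx3cr1 by 1.63, whereas the resting-state genes Tmem119 and P2ry12, given here after their values were seen, were at -1.76 (adjusted p = 2.2e-05) and -1.15 (adjusted p = 3.8e-04). Reactive astrocyte genes rose for 14 of 18 members (15 adjusted over the list alone), median 1.81 (adjusted p = 9.4e-12; adjusted p = 0.076 with an estimated correlation), with Serpina3n at 3.58 ± 0.09 and Gfap at 1.51. General astrocyte genes did not pass as a list, with 5 up and 2 down of 16, also adjusted over the list alone (adjusted p = 0.11). Sox9 rose by 0.78 and the amino acid transporter Slc7a10 fell by 0.53. Of 19 interferon response genes 4 rose, also adjusted over the list alone (adjusted p = 0.16, median 0.08). These included Lgals3bp (1.94), Ifitm3, which blocks viral entry (1.01), and the tetherin gene Bst2 (1.48). In cHET 3, Cxcl10 was 105 and Ifit1, an antiviral RNA-binding protein, was 285, each the highest of its group, and without cHET 3 the interferon response list passed (median 0.48, adjusted p = 3.9e-04). Antigen presentation genes rose for 12 of 14 members, also adjusted over the list alone (adjusted p = 2.5e-09; adjusted p = 0.068 with an estimated correlation), with Cd74, the invariant chain of MHC class II, at 4.15 ± 0.32.

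Of 21 integrated stress response genes 7 rose and 3 fell (8 and 3 adjusted over the list alone; adjusted p = 0.12), with Atf3 at 3.26 and Psat1, an enzyme of serine synthesis, at -0.60. Of 12 endoplasmic reticulum chaperones 4 rose, also adjusted over the list alone (adjusted p = 0.017; adjusted p = 0.45 with an estimated correlation), led by Edem1, a factor of glycoprotein degradation (1.01). Necroptosis genes rose for 4 of 8 members (5 adjusted over the list alone; adjusted p = 9.5e-03, and adjusted p = 0.18 with an estimated correlation), with Casp8 at 1.23. Of 12 tested p53 targets 5 rose (6 adjusted over the list alone; adjusted p = 0.026, and adjusted p = 0.27 with an estimated correlation), for example Ccng1 (cyclin G1) by 0.81 and Phlda3, an inhibitor of AKT, by 0.64. In the authors' deposited table Cdkn1a was at 1.36 (q = 5.8e-06) and Plk2 at -0.04 (q = 0.83). Immediate early genes rose for 7 of 10 members and fell for 1, also adjusted over the list alone (adjusted p = 2.3e-03; adjusted p = 0.17 with an estimated correlation), with Fos at 1.19 and Jun at 0.75.

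Neuronal genes fell for 6 of 17 members, also adjusted over the list alone, median -0.13 (adjusted p = 6.1e-03; adjusted p = 0.47 with an estimated correlation), with Syt1, a synaptic vesicle calcium sensor, at -0.51 and Gad1 at -0.73. Of 5 motor neuron genes 1 rose, also adjusted over the list alone (adjusted p = 0.41 for the list). It was Calca, a neuropeptide gene named here after its value was seen (1.10, adjusted p = 2.0e-03). Chat, Slc5a7 and Prph are missing from the per-library values or differ there. In the authors' deposited table they were at -0.06, 0.37 and 0.03 (q = 0.73, 1.8e-03 and 0.88). Endothelial and mural genes gave 3 up and 3 down of 18 (4 and 4 adjusted over the list alone; adjusted p = 0.76, test downward, median -0.09, mean 0.15), with the peptidase Anpep at 2.09. None of 10 meningeal fibroblast genes was called by limma (0 adjusted over the list alone; adjusted p = 0.53, median -0.18). For Schwann cells 3 of 8 genes rose and 1 fell, also adjusted over the list alone (adjusted p = 0.61, test upward, median -0.31, mean -0.11). Without cHET 2, whose mean over the Schwann cell list was 7.34 against 5.64 and 5.17 in cHET 1 and 3, the median was 0.37 (adjusted p = 0.31). The adhesion molecule Cdh19 rose by 1.68 and Pmp22 fell by 0.89. Ptprc (2.84, adjusted p = 3.5e-07) was the 1 gene of 8 that rose in the peripheral leukocyte list, also adjusted over the list alone (adjusted p = 0.40 for the list). Erythrocyte and sex-linked genes held no call in 5 and 8 members (0 each adjusted over the list alone; adjusted p = 0.57, median -0.34, and adjusted p = 0.91, median 0.06). Of 21 disease-linked genes 3 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.62, test downward, median -0.05, mean 0.03), with Grn at 2.0 and Unc13a, a synaptic priming factor, at -0.56.

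**Figure D3:**
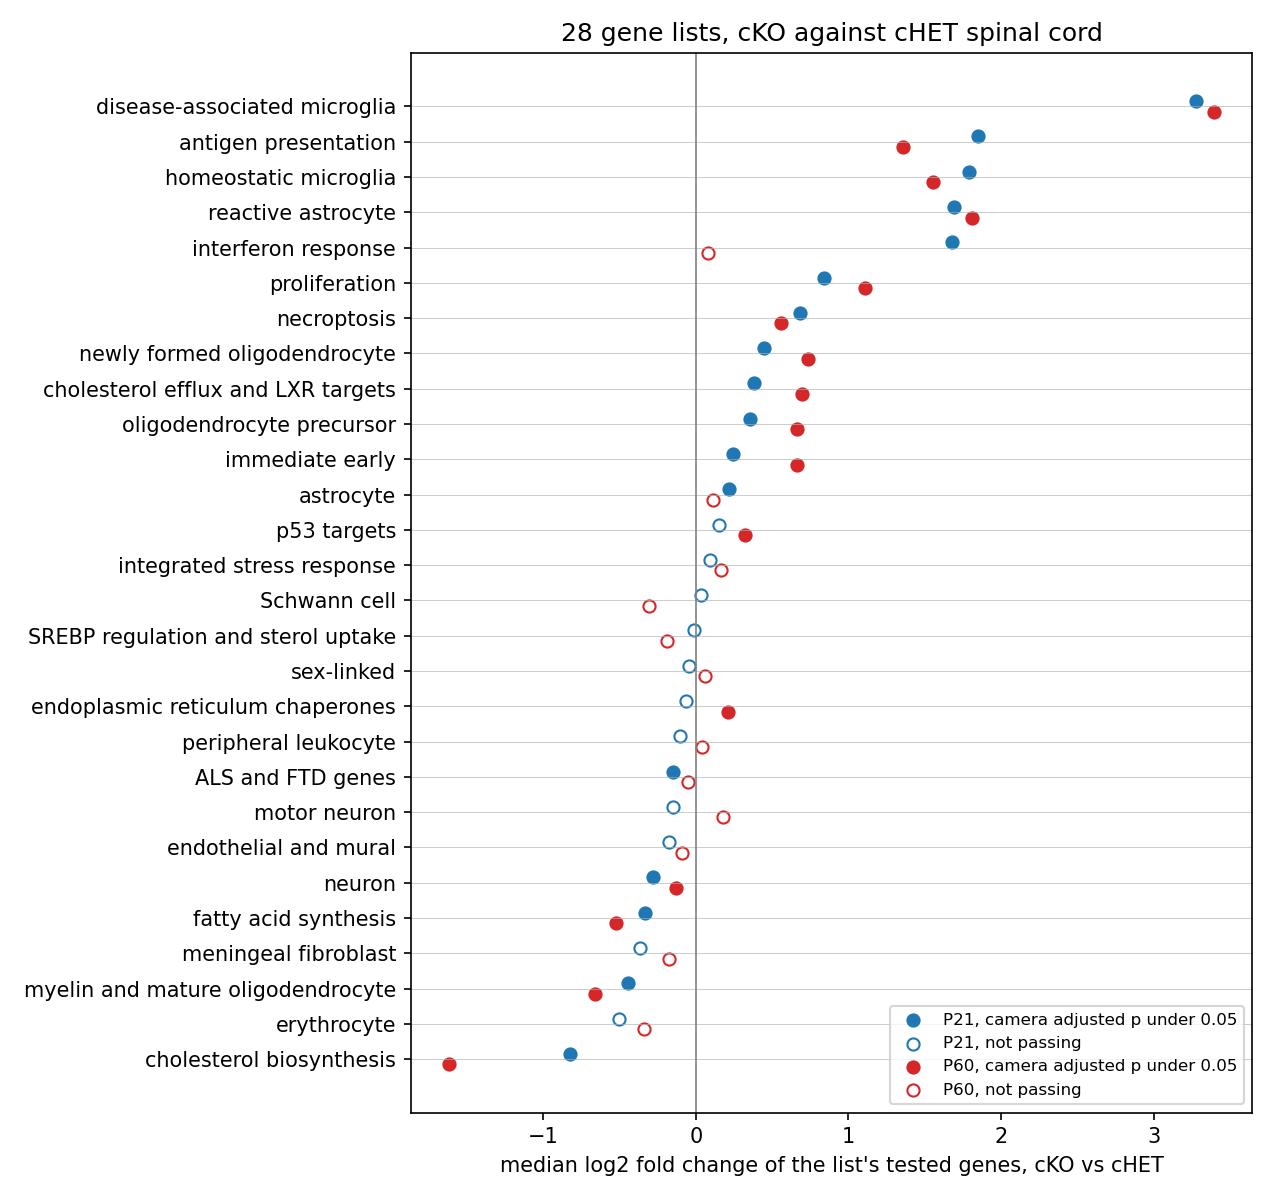
Median log2 fold change of cKO against cHET for each of the 28 gene lists at P21 and P60, filled where the list test with a preset correlation passed. The disease-associated microglia list has the highest median at both ages (3.28 and 3.40) and cholesterol biosynthesis the lowest (-0.82 and -1.62).

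**Figure D4:**
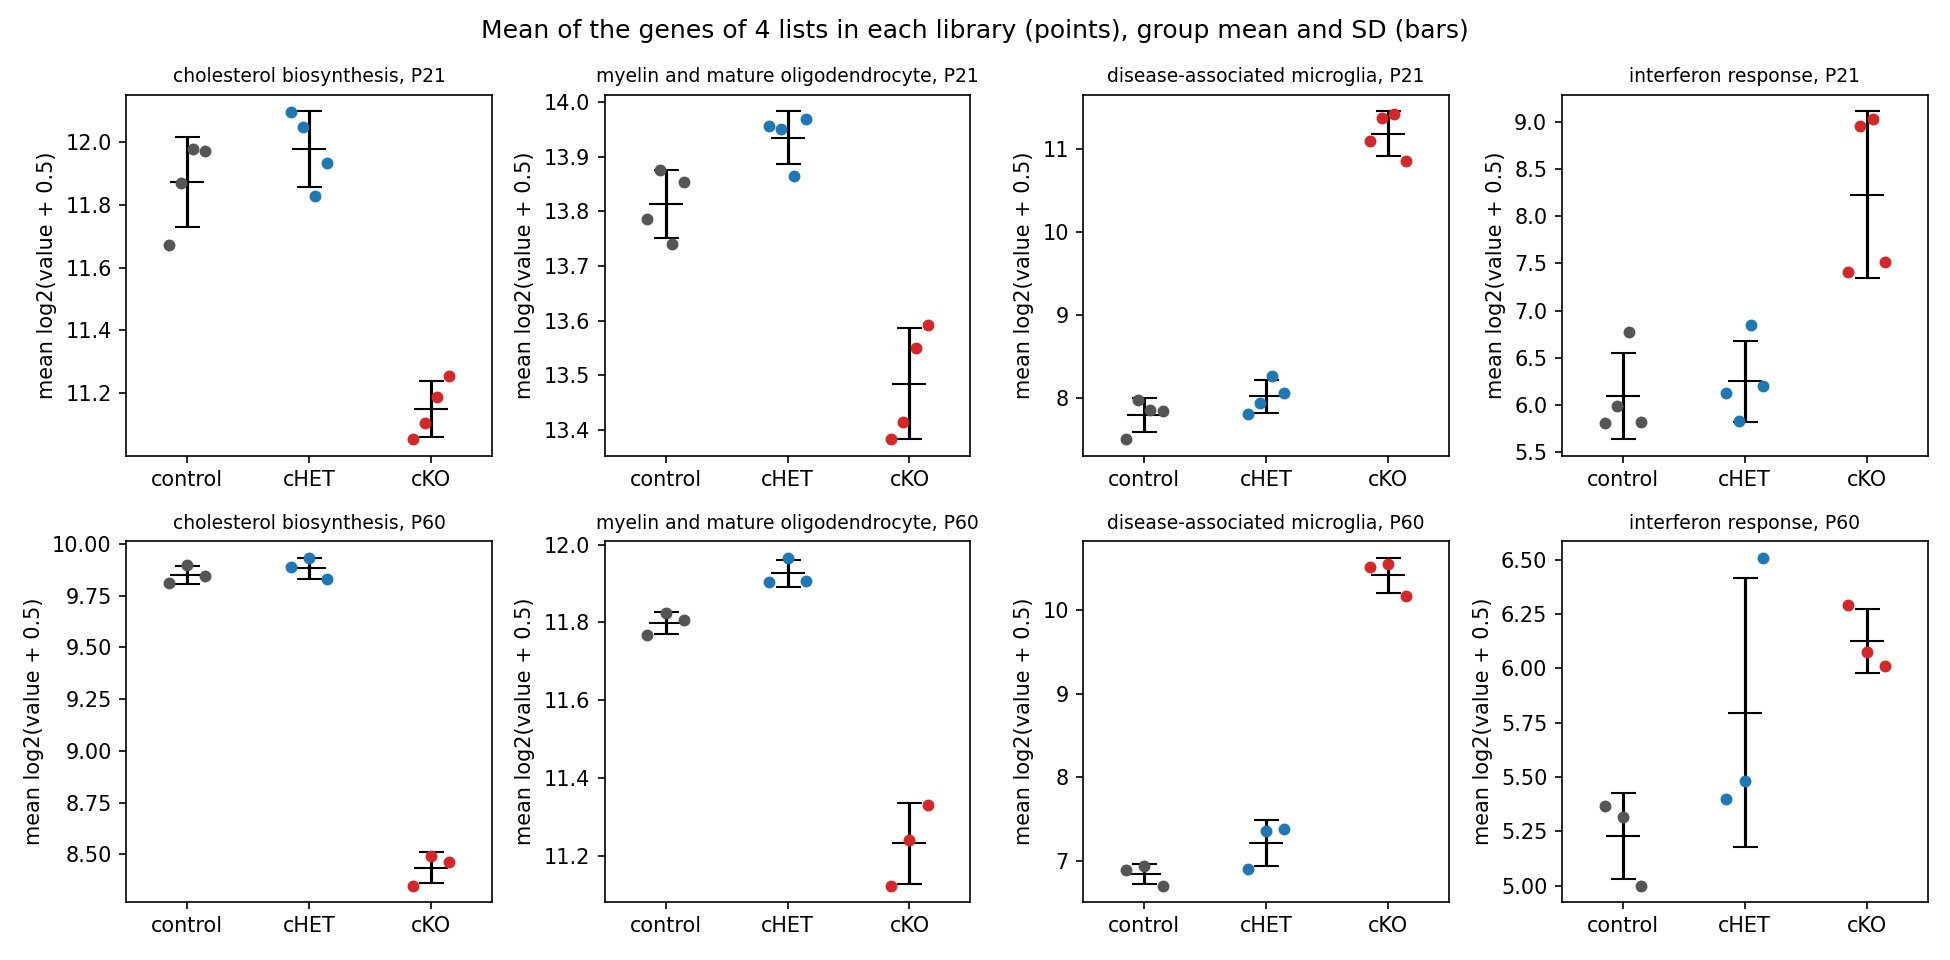
Mean log2(value + 0.5) of 4 gene lists (cholesterol biosynthesis, myelin and mature oligodendrocyte, disease-associated microglia, interferon response) in each library by genotype and age, with the mean and SD of each group. The cKO libraries lie apart from both other genotypes for the cholesterol and microglia lists at both ages.

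Control mice have intact Tardbp and no Cre, so cKO against control adds the effect of Cnp-Cre to that of the deletion. At P21 the leading genes were again Wisp2 (7.17 ± 0.59, adjusted p = 5.5e-07), Itgax (6.01), Atp6v0d2 (6.09), Hcar2, a receptor for hydroxy acids (6.19), and Bcl2a1d, an antiapoptotic gene (6.09). Nkx2-9 fell by 4.30 ± 0.17 and Klk6 by 3.46 ± 0.20. Of the other genes at the lower end, Rps27a-ps2 (-7.91) and Gm26920 (-5.43) are uncertain, and Gm49387 was listed at 0 in every cKO library. In all 4834 of 17989 genes changed, 2620 up and 2214 down, with 846 up and 111 down by at least 2-fold, and the groups did not overlap for 27.4% of the genes against 2.86% by chance. The upward share of 54.2% became 43.5% after quantile normalization (2313 up, 3002 down). The authors' deposited table holds 5126 genes with q under 0.05 (2753 up, 2373 down), including 94.3% of the genes called here. At P60 Atp6v0d2 (8.0), Arsi (7.76), Cst7 (7.72 ± 0.38), Cd300lb (7.09) and Lilrb4a (6.94) led the increases, and Nkx2-9 (-6.21 ± 0.20) the decreases, beside the uncertain AL670603.1 (-5.97), Apoo-ps (-6.24), Gm10123 and Rpl31-ps8. There 4360 of 16833 genes changed, 2435 up and 1925 down, 923 and 287 of them by at least 2-fold, without overlap for 40.8% of the genes against 10% by chance. The upward share was 55.8%, and 45.2% after quantile normalization (2160 up, 2620 down). The authors' deposited table holds 4545 genes there (2511 up, 2034 down), including 91.1% of those called here. At P60 the age in days differs between the controls and the cKO mice and cannot be separated from genotype. The labelled sex differs too, yet the P60 controls expressed 4 Y-linked genes at 82.9% to 91.4% of the mean of the P60 libraries labelled male, so the label and the libraries do not match.

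By gene list, cholesterol biosynthesis fell for 19 of 20 members at P21 (20 adjusted over the list alone; adjusted p = 6.2e-17, and adjusted p = 0.10 with an estimated correlation). At P60 it fell for 20 of 20, also adjusted over the list alone (adjusted p = 4.5e-24; adjusted p = 0.046 with an estimated correlation). Mature oligodendrocyte genes fell for 13 and rose for 5 of 25 at P21 (16 and 6 adjusted over the list alone; adjusted p = 7.9e-05, and adjusted p = 0.28 with an estimated correlation). The P60 counts were 16 down and 3 up (17 and 3 adjusted over the list alone; adjusted p = 6.9e-07, and adjusted p = 0.17 with an estimated correlation). Disease-associated microglia genes rose for 22 of 23 and 21 of 22 members (23 and 21 adjusted over the list alone), with adjusted p = 4.3e-30 and 1.9e-23, and passed at both ages with an estimated correlation (adjusted p = 0.031 and 0.046). At P21 18 lists passed, of which reactive astrocytes (adjusted p = 0.013) and disease-associated microglia also passed with an estimated correlation. At P60 19 passed, of which cholesterol biosynthesis, newly formed oligodendrocytes, precursors, disease-associated microglia and antigen presentation did so (adjusted p = 0.046 each). Interferon response genes rose for 17 of 19 at P21 (19 adjusted over the list alone; adjusted p = 7.1e-10, and adjusted p = 0.21 with an estimated correlation). At P60 6 rose, and the list passed (adjusted p = 8.3e-04; adjusted p = 0.42 with an estimated correlation). Endothelial and mural genes fell for 9 and rose for 2 of 18 at P21 (11 and 2 adjusted over the list alone; adjusted p = 7.6e-03, and adjusted p = 0.41 with an estimated correlation). The P21 lists of SREBP regulation (test downward, median 0.05, mean -0.06), peripheral leukocytes (upward, -0.02, 0.12) and sex-linked genes (downward, 0.05, 0.17) differed in sign, as did the P60 lists of motor neurons (downward, 0.11, 0.05), endothelial and mural cells (downward, -0.10, 0.11) and disease-linked genes (downward, -0.05, 0.06). At P60 all 5 erythrocyte genes were lower adjusted over the list alone and 3 over all genes (adjusted p = 0.015, median -1.53; adjusted p = 0.40 with an estimated correlation), beside 10083 for Hbb-bs, a beta-globin, in control 1. Without control 1 the median of the erythrocyte list was -0.86 (adjusted p = 0.032). The P60 p53 list passed (adjusted p = 0.023; adjusted p = 0.29 with an estimated correlation) but not without control 1 (adjusted p = 0.0516). The P21 disease gene list (adjusted p = 0.028; adjusted p = 0.21 with an estimated correlation) did not pass after quantile normalization (0.148) or without cKO 1 (0.050).

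The cHET and control mice differ by Cnp-Cre and by 1 deleted allele, and at P60 also by age in days, which cannot be separated from genotype there. The labelled sex differs at P60 too. Yet the P60 controls expressed 4 Y-linked genes at 82.9% to 91.4% of the mean of the P60 libraries labelled male. No P21 library labelled female exceeded 9.08%, so these values argue against a sex difference between the P60 groups. Beyond Cnp, Hapln2 rose at P21 from 6455 ± 424 to 8728 ± 502 (SD, n = 4; 0.44 ± 0.06, adjusted p = 0.039), and at P60 Bcas1 rose from 5293 ± 347 to 7650 ± 286 (SD, n = 3; 0.53 ± 0.06, adjusted p = 0.026) together with the unnamed gene Gm15800 (0.58 ± 0.07, adjusted p = 0.026). These were the only calls by limma, 2 of 17989 genes at P21 and 3 of 16833 at P60, Cnp included. The P21 count rose to 26 without cHET 4 and to 15 with array weights. With an unadjusted p under 0.05 there were 1284 and 912 genes, and the authors' deposited table holds 35 and 14 at q under 0.05. The groups did not overlap for 5.13% of the genes at P21 and 10.2% at P60, against 2.86% and 10% by chance. Calls of Bcas1 and Gm15800 each ended in 7 of the 9 fits without 1 library, and that of Hapln2 in 8 of 12, which were those without control 1, 3 or 4, cHET 1, 2 or 3, and cKO 1 or 3. It also ended with sex as a covariate, without a filter on low values, with all 6 groups in one fit and after quantile normalization (adjusted p = 0.0605). A fit of only the 2 groups compared kept Cnp alone of these calls at each age, 1 of 2 at P21 and 1 of 3 at P60.

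Of the 28 lists, 5 passed at P21 with the preset correlation and 0 with an estimated one (adjusted p = 0.92 each). Myelin genes were higher (1 of 25 called, 2 adjusted over the list alone; adjusted p = 1.2e-06, median 0.13). Cholesterol biosynthesis (adjusted p = 7.2e-04, median 0.08) and disease-associated microglia (adjusted p = 1.5e-03, median 0.16) lay slightly higher, and endothelial and mural genes (adjusted p = 6.2e-04, median -0.15) and immediate early genes (adjusted p = 5.3e-03, median -0.19) lower, with 0 members called by limma over all genes and 0, 0, 1 and 0 adjusted over the list alone. The cholesterol biosynthesis list did not pass without control 1 (adjusted p = 0.551) or cHET 1 (0.0887), the microglia list without control 1 (0.146) or cHET 3 (0.13), and the immediate early list without control 1 (0.141), cHET 2 (0.156) or cHET 3 (0.13). Test, median and mean differed in sign for necroptosis (downward, 0.05, -0.13) and narrowly for precursors and disease-linked genes. At P60 10 lists passed, 1 of them with an estimated correlation. That list was newly formed oligodendrocytes (1 of 10 up, 3 adjusted over the list alone; adjusted p = 2.8e-06, median 0.15, and adjusted p = 0.046 with an estimated correlation). Myelin genes (adjusted p = 2.8e-06, median 0.12; adjusted p = 0.33 with an estimated correlation) and interferon response genes (adjusted p = 2.8e-06, median 0.54; adjusted p = 0.58 with an estimated correlation) lay higher, the latter not without cHET 3 (adjusted p = 0.216). Genes of the erythrocyte list lay lower (adjusted p = 1.3e-05, median -1.20; adjusted p = 0.33 with an estimated correlation), with a median of -0.51 without control 1 (adjusted p = 9.6e-03). The other lists that passed were Schwann cells (adjusted p = 7.4e-03; 0.383 without cHET 2), disease-associated microglia (8.4e-03; 0.157 without cHET 2, 0.075 without cHET 3), homeostatic microglia (0.018; 0.339 without control 3, 0.216 without cHET 3) and sex-linked genes (0.020; 0.0713 without control 2, 0.0563 without cHET 2, 0.216 without cHET 3). Motor neurons (0.020; 0.146 without control 2, 0.0637 without control 3, 0.0975 without cHET 3) and astrocytes (0.035; 0.163 without control 1, 0.155 without control 2, 0.0623 without cHET 1, 0.338 without cHET 2) passed too. With an estimated correlation the adjusted p of these lists was 0.33 for Schwann cells, sex-linked genes and motor neurons and 0.72 for microglia and astrocytes. Over all genes Bcas1, of the newly formed oligodendrocyte list, was the only member of the passing lists called by limma at P60. Adjusted over the list alone 3 myelin and 2 disease-associated microglia genes were higher and 1 motor neuron gene lower. The tests of peripheral leukocytes (downward, median 0.02, mean -0.06) and proliferation (downward, -0.06, 0.05) differed in sign from a summary. Overlap in the same direction of the calls of cKO and of cHET against the shared controls was 1 gene at each age, Cnp. Independent lists would give 0.269 and 0.404. Simulated unchanged groups gave 0, but they held on average 0 calls at P21, and 0.2 for cKO and 0.05 for cHET at P60. Their overlap is therefore no baseline. Hapln2 at P21 and Bcas1 at P60 were called in opposite directions, lower in cKO and higher in cHET. The 2 sets of log2 changes correlated across genes, which are not independent replicates, at 0.324 at P21 and 0.331 at P60, against 0.501 and 0.508 in simulated unchanged groups. The simulated correlation comes from the shared controls alone, without any genotype change, so it is no baseline for the changes of cKO. The covariance of the 2 observed sets was 0.0784 and 0.0867 against 0.0618 and 0.0657 simulated. With the P21 controls split into 2 sets the correlation was 0.0801 and the overlap 1.33 genes. The 3 P60 controls were too few to split, so part of the P60 value may come from the shared controls.

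Genes called in cKO against cHET at both ages numbered 2455 in the same direction among 16570 tested at both. Of these 1479 rose, against 300.4 for independent lists, and 976 fell, against 206.2, while 25 went opposite ways (one-sided Fisher exact p below 1e-300 in each direction, over genes, which are not independent). A test of the difference itself called 507 of 18695 genes, 238 with a higher and 269 with a lower log2 change at P60. Syt4, a synaptotagmin, had the smallest p (difference 1.78 ± 0.11, adjusted p = 5.6e-09), moving from -0.32 at P21 to 1.46 at P60. Ngfr, the low-affinity neurotrophin receptor (2.55 ± 0.18), Cyp26b1, which degrades retinoic acid (2.78 ± 0.22), Mcam, an adhesion molecule of vessels (1.02), Col27a1, a fibrillar collagen (1.29), and Poc1a, a centriole protein (2.51), differed upward. Hapln2 (-1.85 ± 0.12, adjusted p = 1.6e-08), Anln (-2.26), Myoc, myocilin (-2.22), and Ccdc187 (-2.01) differed downward. Of the genes named above, Insig1 (-1.36), Stard4 (-1.31), Fdft1 (-1.31), Msmo1 (-1.18) and Sqle (-1.0) fell further at P60, and Apoe (1.16) and Abca1 (1.19) rose further. Age coincides with the library kit, so an age difference and a kit difference cannot be told apart, and leaving out single libraries gave 371 to 656 genes.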

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

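The tests in the next 3 paragraphs were written after the results were seen, and the regrouping counts that follow were set before, except the last of them.

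The cholesterol biosynthesis genes could be lower in cKO cord because the cord holds less oligodendrocyte RNA. At P60 the median of the cholesterol list lay 0.96 below that of the mature oligodendrocyte list, which speaks against that share as the whole cause. The 95% bootstrap interval was 0.58 to 1.28. It came from drawing the genes of each list anew 2000 times, not the mice, so it holds no variation between animals and treats genes as independent. The authors' normalization is an unlikely cause, since the list median stayed at -1.63 or lower under every other scaling. Genes whose values differ between the 2 kinds of file are unlikely to be the cause, since 100% of the 17 members with equal values in both were lower. Whether SREBF2 activity was lower is not settled by these values, and the cause is left open.

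Per-library values that do not give the authors' mean lay mostly on chromosomes 13 to 17, where 40.1% of genes differed or were absent at P21 against 1.89% elsewhere, and 41.3% against 1.98% at P60. Another annotation behind the per-library values may be the reason, because 89.1% of the 220 placed identifiers newer than any in the authors' tables lie on these chromosomes. Rounding or another normalization would not favour some chromosomes by 38.3 points. At P60, 184 of the 4200 genes called for cKO against cHET were among the 826 tested genes with differing values. Restricting the called share there to genes with equal means, which also drops genes absent from the authors' tables, moved it by 0.741 points. The 15215 genes with equal means are most of the 16833 tested. That shift therefore cannot settle whether differing genes decide the calls. Genes absent from the per-library values could not be tested.

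All 3 P60 control libraries, labelled female, expressed 4 Y-linked genes at 82.9% to 91.4% of the mean of the P60 libraries labelled male, whereas no P21 library labelled female exceeded 9.08%. A sex label that differs from the animals could explain this. A small carry-over of male RNA is unlikely at 82.9%, and an exchange within P60 is unlikely too, since 0 P60 libraries labelled male lacked these genes. At P21, 9 genes differed between male and female mice, with Ddx3y at 6.00 and Kdm5d at 3.04.

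For the number of changed genes at P21, 1 of 35 ways to divide the 8 libraries of cKO and cHET gave as many (4059, highest other 2). For cKO against control it was 1 of 35 as well (4834, highest other 2). These shares speak against chance, but 1 of 35 is the smallest share possible. The other divisions mix genotypes, which widens the spread within groups and lowers their counts, so the gap to 2 is no measure of strength. Chance cannot be excluded for cHET against control (3 of 35, count 2, highest other 7). For the number of passing lists at P21, 23 of 35 gave as many for cHET against control (5, highest other 13), which does not exclude chance. The count was reached in 5 of 35 for cKO against cHET (17, highest other 20). For cKO against control it was reached in 2 of 35 (18, highest other 20). These 2 counts cannot decide, because the other divisions that reached them exchanged only 1 mouse of each genotype and so kept part of the genotype difference. Divisions that exchanged 2 mice of each genotype gave at most 5 lists for cKO against cHET and at most 6 for cKO against control. At P60 the 10 ways to divide 6 libraries are too few for a share under 0.05. The gene counts were 4200 (highest other 2), 4360 (highest other 2) and 3 (highest other 3), reached in 1, 1 and 2 of 10, and the list counts 16 (highest other 14), 19 (highest other 17) and 10 (highest other 11), reached in 1, 1 and 2 of 10. For the age difference 9 of 100 ways gave as many as 507 (highest other 4492), so chance cannot be excluded by this count, in which exchanging labels at one age turns a common genotype effect into an age difference. With the common effect, estimated from the real labels, taken out, 1 of 100 gave as many (502, highest other 115). That version speaks against chance, but it was chosen after the result was seen and does not replace the planned count.

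The change between cKO and cHET differed with age for 507 genes and for 43 of 182 named genes. Higher at P60 were Abca1 (1.19), Apoc1 (2.12), Apoe (1.16), Cd74 (1.70), Cd9 (0.89), Cdh19 (1.19), Col27a1 (1.29), Cyp26b1 (2.78), Gpr17 (1.36), Mcam (1.02), Neu4 (0.61), Ngfr (2.55), Phlda3 (0.62), Poc1a (2.51), Sox10 (0.56), Srebf1 (0.76) and Syt4 (1.78). Lower at P60 were 4933413G19Rik (-1.64), Anln (-2.26), Bcas1 (-0.75), Ccdc187 (-2.01), Cntn2 (-1.14), Cyp51 (-0.53), Ermn (-0.62), Fa2h (-0.59), Fdft1 (-1.31), Gjb1 (-0.99), Gm19963 (-3.40), Hapln2 (-1.85), Hmgcs1 (-0.83), Insig1 (-1.36), Msmo1 (-1.18), Myoc (-2.22), Nkx2-9 (-1.84), Pdlim1 (-2.38), Psat1 (-0.40), Sc5d (-0.82), Serpinb1a (-2.07), Sqle (-1.0) and Stard4 (-1.31). The differences of Rps27a-ps2 (10.52), AL670603.1 (-6.89) and Gm10123 (-7.52) are uncertain.

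Tests of whole lists on the age difference were added after the data were seen, and 10 of 28 passed at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.103). The median difference was -0.68 for cholesterol biosynthesis (adjusted p = 1.4e-22), -0.15 for SREBP regulation and sterol uptake (6.5e-03), 0.21 for cholesterol efflux and LXR targets (6.5e-03), -0.36 for myelin (4.4e-05) and 0.29 for oligodendrocyte precursors (3.9e-05). It was -0.29 for homeostatic microglia (1.5e-03; 0.0797 without P60 cKO 3), -1.63 for interferon response (1.0e-10), 0.21 for endoplasmic reticulum chaperones (0.013; 0.0966 without P21 cHET 4, and not without P21 cKO 4 either), 0.11 for neurons (0.035; 0.187 without P60 cKO 3) and 0.35 for motor neurons (0.035; 0.082 without P21 cKO 1). The last 2 lists lost their call without any 1 of 9 and of 7 libraries, of which the highest value is given. Of the 19 interferon response genes 0 were called for the age difference, and that list did not pass with fry (adjusted p = 0.085). Homeostatic microglia (0.22), endoplasmic reticulum chaperones (0.31), neurons (0.29) and motor neurons (0.12) did not pass with fry either. The other lists given here did, with the highest adjusted p for myelin (0.029).

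Single libraries were compared with the other 3 of their group at P21, where about 1 in 20 tests passes by chance. Of 543 pairs of named gene and group 46 were past the critical value (8.47%), of 84 pairs of list and group 5, and of 12 library measures 1. The measure was the mitochondrial share of P21 cHET 4 (ratio 0.849). The lists were astrocytes in P21 cHET 3 (0.903), p53 targets in P21 cHET 1 (0.881), neurons in P21 cHET 4 (0.832), endothelial and mural genes in P21 control 4 (0.980) and Schwann cells in P21 cHET 3 (0.848). In P21 cHET 1 they were Dnah8 (0.852), Bub1 (0.885), Syt1 (0.879) and Mki67 (0.834). P21 cHET 3 stood apart for Apoc2 (1), Lilrb4a (0.872), Gpnmb (0.914), Cyp27a1 (0.849), Ctss (0.861), Ctsd (0.861), Lyz2 (0.881), Bst2 (0.847) and Oas1a (0.920). For P21 cHET 4 the genes were Slc7a10 (0.872), Phlda3 (0.875), Fos (0.852), Gm10123 (0.872) and Gm15800 (0.888). In P21 cKO 1 they were Gm26920 (1), Ccdc187 (0.838) and Col27a1 (0.913). P21 cKO 2 stood apart for Xpo7 (0.872), Itpr2 (0.861), Cspg4 (0.871) and Neu4 (0.850). For P21 cKO 3 the genes were Stard4 (0.919), Serpinb1a (0.909), Gm19963 (0.907) and Syt4 (0.866). In P21 cKO 4 they were Gpnmb (0.907), Rps27a-ps2 (0.927) and Egr2 (0.905). P21 control 1 stood apart for Cyp51 (0.919), Acss2 (0.890), Aqp4 (0.849), Gad1 (0.871), Ube2c (0.944) and Poc1a (0.836). For P21 control 2 the genes were Xpo7 (1) and Cdh19 (0.937). In P21 control 3 they were Cdkn1c (0.883), Srebf1 (0.988) and Bst2 (0.962). P21 control 4 stood apart for Atp6v0d2 (0.836), Klrb1b (1) and Tyrobp (0.865). All libraries were kept. Xpo7 was 283 in P21 cKO 2, 34 and 36.2 in cKO 1 and 3, and 3.0e-06 in cKO 4.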

How the results depend on the processing

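The alternatives that leave out P60 control 1 with cHET 3, or genes unequal between files, were added after the results were seen. No paired analysis was possible because the labels give each mouse its own number and no replicate number, so the replicate numbers used here are names only. For cHET against control 2 genes changed at P21, 1 without a filter, 1 after quantile normalization, 15 with array weights, 1 with sex as a covariate, 1 with all 6 groups in one fit, 35 in the authors' test, and 1 to 26 when single libraries were left out. At P60 3 changed, 6 with all 6 groups, 14 in the authors' test, and 1 to 4 without single libraries. The overlap of the ages was 2455 genes, 1511 at adjusted p under 0.01 in both, and 2075 to 2484 without single libraries. With an estimated correlation the number of passing lists went from 17 to 2 (P21) and 16 to 0 (P60) for cKO against cHET, from 18 to 2 and 19 to 5 for cKO against control, and from 5 to 0 and 10 to 1 for cHET against control, where fry gave 0 and 1. For cHET against control at P60, 6 lists passed without control 1 and cHET 3 together, not necessarily among those 10. Leaving out single libraries gave 2 to 7 lists for this comparison at P21 and 6 to 11 at P60. The adjusted p of cholesterol biosynthesis with an estimated correlation was 0.061 at P21 (2.1e-21 otherwise) and 0.052 at P60 (1.1e-24 otherwise). For cKO against cHET, Cnp at P21 was 0.17, 0.23 after quantile normalization and 0.13 to 0.22 without single libraries, and Tardbp at P60 was -0.20, with -0.22 to -0.18. Counts of changed genes for cKO against cHET ranged from 3193 to 4019 at P21 and from 3216 to 4153 at P60 without single libraries. After quantile normalization the larger part of the changed genes was lower in all 4 comparisons of cKO, where it had been higher, and the cause was not tested.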

Other observations

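No test was added for the observations below, and the values were read after the results were seen. Interferon genes varied among P21 cKO mice, with Ifit1 at 491 and 522 in the 2 mice labelled male and 176 and 152 in the 2 labelled female. The stress regulator Atf3 and the complement genes rose at both ages, and Srebf1 rose at P60 while Insig1 and Stard4 fell. Opalin rose where Hapln2, Gjb1 and Klk6 fell.

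Among P60 libraries the erythrocyte genes were highest in control 1, where Hbb-bs was 10083, and the P60 mitochondrial share ranged from 10.2% to 17.9%. The rise of Lilrb4a against cHET has no explanation here. The change of Syt4 had opposite signs at the 2 ages, and no cause was tested. The decrease of Nkx2-9 was among the largest at both ages and was not pursued further.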
